A study of Escherichia coli K-12 with 2 samples.

How the data were processed

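Total RNA of Escherichia coli K-12 strain BW25113, a laboratory strain widely used as the parent of gene deletion collections, was compared on 2 two-colour spotted oligonucleotide arrays. Per the labels' protocols, cultures in LB, a rich medium, were grown with shaking at 37 °C to an OD600 of about 0.4 and exposed to tellurite, an oxyanion of the metalloid tellurium that is toxic to bacteria, at 0.5 µg/ml for 15 min. Random-primed cDNA was labelled with Alexa Fluor 555 or Alexa Fluor 647. Each array held RNA of 1 exposed and 1 untreated culture. Exposed RNA was in Alexa Fluor 555 on replicate 1 and in Alexa Fluor 647 on replicate 2, and the labels describe the replicates as independently grown cultures.

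Each deposited array file holds the mean foreground minus background intensity of 10944 spots at 635 nm and 532 nm, per the file headers, so the authors had already subtracted the background. The files also hold the raw log2 ratio of 635 over 532, which was given for 10901 spots of replicate 1 and 10930 spots of replicate 2, and a log2 ratio after loess normalization, per the file headers. The submitters' processing notes name limma; its version, the scanner and the image software are not given in the sources used here. The deposited value table equalled the normalized column of the array files in all 10944 spots of both arrays (tolerance 1e-06). These normalized values were obtained again, for all 10944 spots of each array and to the same tolerance, from the deposited intensities with limma's normexp correction at an offset of 50 and a global loess curve through all spots. Normalized values in the deposited files are 635 over 532, so they point from tellurite to untreated on replicate 1 and from untreated to tellurite on replicate 2, and their medians are -0.0018 and 0.0012.

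From the deposited intensities, log2 ratios were computed with limma 3.58.1 in R 4.3.3. The normexp model (offset 50) was fitted to all spots. A global loess curve (span 0.3) was fitted within each array with control and empty spots at weight 0, which is the only step that differs from the deposited values. Ratios were turned to tellurite over untreated by the dyes in the labels and were not scaled between arrays. Spots with the same name were averaged, which left 10143 probe names. The mean ratio of the 2 arrays was tested against 0 with limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over the 10143 probes and a threshold of 0.05. The fit had 1 residual degree of freedom per probe, to which the prior added 3.04. A dye term would have used that degree of freedom, so a dye effect of single probes stays in the spread between the arrays. Probes at 2-fold or more with the same sign on both arrays were also counted, beside the mean count over 1000 shuffles of replicate 2 among probes within 20 bins of brightness. The number of arrays limits the precision of every value.

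Probe names are oligonucleotide codes that the files do not pair with genes, and 0 of the 10143 names matched an identifier, symbol or synonym among the 4651 genes of the K-12 MG1655 reference table. The 24 gene lists (703 genes) fixed before the data were examined, and every test of them, were therefore not run, and no genomic position is given. Probes are grouped here only by how their codes begin: 5978 names in a series starting with E1, numbered without gaps, 3330 in a series starting with E2, 770 starting with opEcco and 65 codes of the E1 series with an added suffix. What these codes stand for is not stated. The rule for named items, also fixed beforehand, takes 12 per direction, filled where fewer pass by the largest smaller ratio of the 2 arrays; without gene names it was limited to the first 2 per direction.

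The method was tested on simulated data with 100 probes changed 2-fold and 100 changed 4-fold, with noise drawn from the difference between the arrays. This noise was taken from all spots and redrawn within 20 bins of brightness, separately for each array. It included the 32 dye marker spots, with median log2 ratios of 6.28 and -6.39 on replicates 1 and 2, which the fit of the real data left out. The counts recovered therefore do not measure power on the real probes. The moderated test with 1 prior variance recovered 0 of 100 at either size. With a prior that followed brightness and was robust to outliers, 7 of 100 were recovered at 2-fold and 47 of 100 at 4-fold, with 0 false calls. The simulated noise differed among probes only by brightness, as that prior assumes, and held no error shared by the arrays. The simulation therefore cannot decide between the 2 priors or give the false calls in the real data. Alternatives were plain subtraction, median centring, scaling between arrays, the deposited table, the median of spots, the brightness-dependent robust prior, a test against 1.5-fold, other thresholds and each array alone. A filter on probes above empty spots, loess within 32 inferred printing blocks of 342 spots, and the trend and robust priors singly were added after seeing the data. The files hold no separate background, background SD, spot flags, median foreground or stated blocks, so the alternatives that need them were not run.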

Results

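Transcript levels of E. coli K-12 BW25113 were measured after 15 min of exposure to 0.5 µg/ml tellurite and in untreated cultures, with 2 cultures per condition on 2 arrays of opposite dye orientation. The median net signal of the 10234 probe spots was 826 for exposed and 507 for untreated RNA on replicate 1, and 952 and 775 on replicate 2. Empty spots had median net signals of 129 and 50.5 on replicate 1 and 123 and 152 on replicate 2, in the same order. The highest signals lay between 57080 and 61498 in the 4 channels. The 32 dye marker spots were bright at 532 nm on both arrays, with medians of 18237 and 21656, and dim at 635 nm, with medians of 138 and 289, so the channel columns of both files were in the same order.

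The comparison of exposed with untreated cultures asked which transcripts differ after a short exposure to tellurite. A small set of probes showed large ratios of the same sign on both arrays. Of 10143 probes, 69 were at least 2-fold higher and 22 at least 2-fold lower in exposed cells on both arrays, 91 in all, against a mean of 39.2 when probes of similar brightness were shuffled. Another 45 were at 2-fold or more with opposite signs, against 40.4 in the shuffles. Among the 6923 probes brighter than the 95th percentile of empty spots on both arrays, 52 were higher and 16 lower, 68 in all against 12.2 in the shuffles, and 10 had opposite signs. The highest of 1000 shuffles of these brighter probes gave 24. Taken alone, replicate 1 had 583 probes higher and 235 lower at 2-fold or more, and replicate 2 had 376 and 370. Among probes above empty spots the values were 274 and 97 on replicate 1 and 192 and 158 on replicate 2. The shuffles, which keep each array's own distribution, gave 76.4% higher among the brighter probes, where 76.5% were observed. Of the 326 empty spots, 6 (1.84%) also met the 2-fold criterion on both arrays, all of them higher. This share was above the 0.90% of all probes and the 0.98% of probes above empty spots.

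The 2 probes with the largest ratios above untreated were E100003954 and E100001199, both of the E1 series. E100003954 had a mean log2 ratio of 3.24 ± 0.10 (SD, n = 2), or 9.43-fold, with net signals of 20223 and 10661 in exposed and 1721 and 788 in untreated cultures. E100001199 had a mean log2 ratio of 3.05 ± 0.54 (SD, n = 2), or 8.28-fold, with net signals of 9023 and 6543 against 642 and 699. The 2 probes with the largest ratios below untreated were E100003478 and E100003592. E100003478 had a mean log2 ratio of -2.42 ± 0.13 (SD, n = 2) and went from 14231 and 4613 in untreated to 2893 and 1360 in exposed cultures. E100003592 had a mean log2 ratio of -2.41 ± 0.21 (SD, n = 2), with net signals of 17110 and 5447 against 4084 and 1380. The genes of these 4 probes are not paired with their codes in the files.

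No probe passed the adjusted threshold in limma's moderated test with 1 prior variance, where the smallest adjusted p was 0.739 (also that of the 4 named probes, with standard errors of 0.22 to 0.29); 673 probes had an unadjusted p under 0.05, against 507 by chance. With the prior variance following brightness and robust to outliers, limma called 58 probes, 38 higher and 20 lower, all with the same sign on both arrays and 44 of them at 2-fold or more on both. Their absolute mean log2 ratios ran from 0.60 to 3.24, with a median of 1.44. In that fit the adjusted p (limma, Benjamini-Hochberg) was 2.7e-05 for E100003954, 0.00063 for E100001199 and 0.00018 for both E100003478 and E100003592. The same fit on ratios left unturned, which compares dyes and not treatments, called 0 probes. The fit with 1 prior variance also called 0, with 299 at an unadjusted p under 0.05, below the 507 by chance. Ratios shared by the arrays widen the spread in the unturned fits, so these low counts do not measure false calls among the 58. In simulated data the fit with 1 prior variance recovered 0 of 100 probes changed 4-fold. The simulated noise also came from dye marker and other control spots, so the power of this fit on the real probes was not measured.

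**Figure D1:**
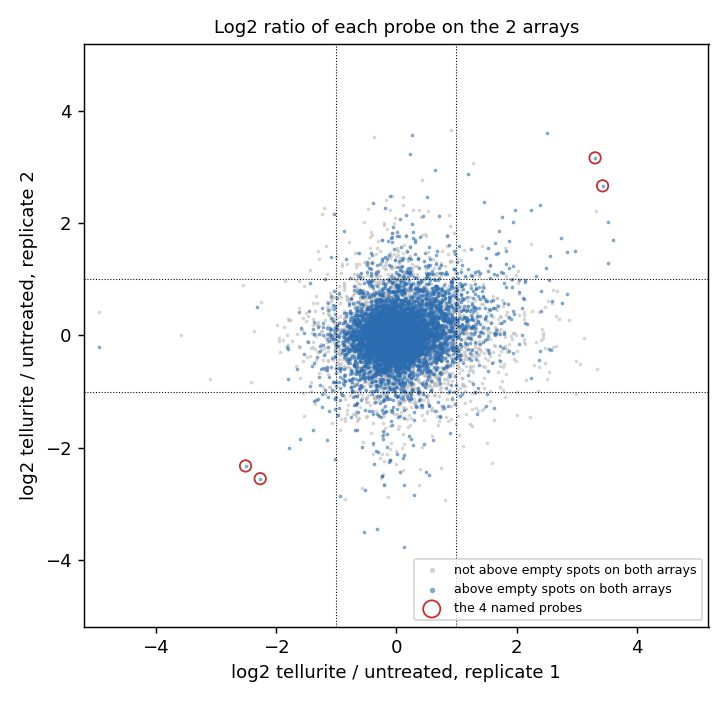
Log2 ratio of tellurite over untreated for each of 10143 probes on replicate 1 (x axis) and replicate 2 (y axis); blue points are the 6923 probes above empty spots on both arrays, grey points the others, red circles the 4 named probes, and dotted lines mark 2-fold. Most probes lie around 0 on both axes, and the upper right corner holds 69 probes against 22 in the lower left.

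Pearson's correlation between the ratios of the 2 arrays was higher for brighter probes, while rank correlation and the share of probes with the same sign were not highest in the brightest ones. Across all 10143 probes the log2 ratios of the arrays had a Pearson r of 0.127 and a Spearman rho of 0.098, with 52.9% of probes of the same sign; probes are not independent replicates. With median centring in place of loess this r was 0.0353. In the dimmest eighth of probes r was -0.0037 and the SD between the arrays was 0.750. In the brightest eighth r was 0.490 and the SD 0.236. Spearman's rho was 0.233 in the sixth eighth, 0.185 in the seventh and 0.109 in the brightest, and the share of the same sign was 56.5%, 55.3% and 50.6%. In the brightest eighth r was 0.199 over the 1248 probes left without those whose mean ratio reached 2-fold. That cut drops large ratios of the same sign and keeps those of opposite signs that cancel. A lower r was therefore likely whatever the cause. Empty spots had an r of -0.010.

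**Figure D2:**
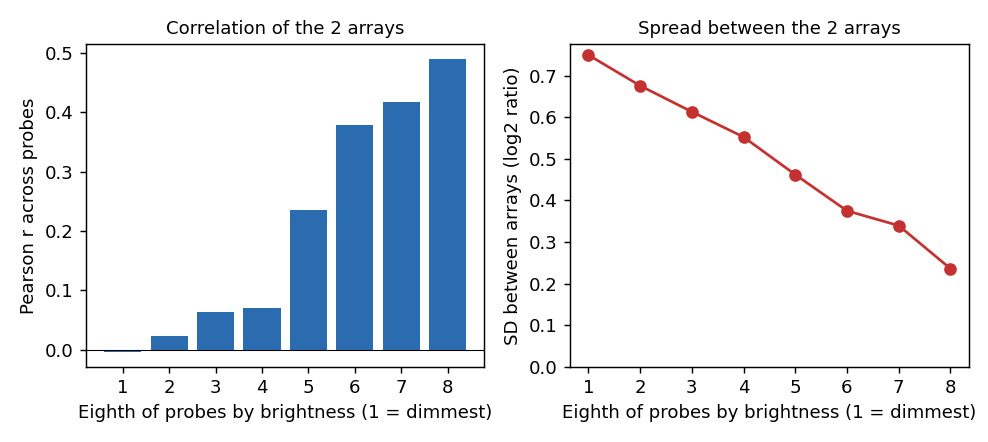
Left, Pearson r between the log2 ratios of the 2 arrays (y axis) within each eighth of the 10143 probes ordered by mean log2 intensity (x axis, 1 is the dimmest); right, SD between the 2 arrays in log2 units for the same eighths. The correlation goes from -0.0037 to 0.490 and the SD from 0.750 to 0.236 between the dimmest and the brightest eighth.

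Among probes above empty spots, the series differed in how many large ratios they held. Of these probes, 57 of 4314 of the E1 series were at 2-fold or more on both arrays, 42 higher and 15 lower, against 7.88 in the shuffles. In the E2 series 11 of 2175 were, 10 higher and 1 lower, against a mean of 3.37 and a highest value of 11 in the shuffles. The opEcco series held 0 of 400, against 0.949 in the shuffles. Without the brightness filter the counts were 72 of 5978 for E1 against 21.2 in the shuffles, 14 of 3330 for E2 against 12.7, and 5 of 770 for opEcco against 5.92, and of these 3 counts only that of E1 lay above the highest of its shuffles (36). Among probes above empty spots, the E1 share exceeded the E2 share with an odds ratio of 2.63 (95% interval 1.36 to 5.58). Fisher's exact test, two-sided, gave p = 0.0018, adjusted 0.0035 over 2 comparisons. The E1 share also exceeded the opEcco share, with an adjusted p of 0.014 in the same exact test (lower 95% limit of the odds ratio 1.40). Shares without the brightness filter were not compared by a test. Of the 58 probes called with the brightness-dependent robust prior, 49 were of the E1 series, 9 of the E2 series and 0 of the opEcco series. The correlation of the arrays among probes above empty spots was 0.300 in the E1 and 0.165 in the E2 series, a difference of 0.135 (permutation of the series within bins of brightness, two-sided, p = 3e-04, 10000 permutations). In the brightest eighth r was 0.601 in the E1 series (rho 0.243) and 0.029 in the E2 series (rho -0.161). These tests treat probes as independent, which they are not. The comparisons of series were not among the analyses fixed before the data were examined. The brightness filter they use was added after seeing the data.

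Repeated spots gave the spread of single spots within an array. The 13 probes of the E1 series printed 3 times had SDs between spots of 0.263 and 0.277 in log2 ratio on replicates 1 and 2. The means of the 3 spots of these probes had an SD of 0.359 between the arrays. That value is for averaged spots and also holds dye and array effects, so it is not on the scale of the SDs between single spots. Their brightness varied more than their ratio, with SDs of 0.839 and 0.763 in log2 intensity between spots of 1 array. Log2 signals of exposed and untreated RNA correlated at 0.923 and 0.953 within an array. Across arrays, r was 0.564 for exposed and 0.580 for untreated RNA.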

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

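Signal above the level of empty spots was present in control spots that the comparison did not use. Of 140 spots with names starting with Alien, 66 exceeded the 95th percentile of empty spots in all 4 channels. Of 24 control spots named by a foreign accession and a gene symbol, 8 did, and of 60 further control spots 17 did. For comparison, 60.6% of the E1 spots, 52.6% of the E2 spots, 42.6% of the opEcco spots and 0 of 326 empty spots did. Whether RNA matching any control was added to the samples is not stated. Median log2 ratios of tellurite over untreated in these 3 kinds of control lay between -0.066 and 0.052 on both arrays.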

How the results depend on the processing

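The count of probes past the adjusted threshold was 0 and stayed 0 with plain subtraction, scaling between arrays, the deposited table, the median of spots, a test against 1.5-fold, an adjusted p under 0.10, loess within inferred printing blocks, the robust prior alone and only probes above empty spots (the last 3 chosen after seeing the data). It was 3 with median centring, 58 with the trend and robust prior, 75 with the trend alone (also added later, holding all of the 58) and 673 at an unadjusted p under 0.05. The trend lets the prior variance fall with brightness, as the spread between the arrays did. The counts of probes at 2-fold or more on both arrays stayed within 1.5 times of 69 higher and 22 lower in every setting that used both arrays; 1 array alone had 376 to 583 higher and 235 to 370 lower, with no test. The correlation of the arrays was 0.107 with plain subtraction, 0.0353 with median centring and 0.250 for only probes above empty spots; the cause was not tested. The 4 named probes kept their direction in all 9 settings each, with mean log2 ratios of 3.17 to 3.31, 2.67 to 3.43, -2.51 to -2.33 and -2.55 to -2.26 in the order of the text. Their direction on each array alone was fixed by how they were picked. The median of spots and the filter on probes above empty spots left their values unchanged. Quantile normalization of brightness between arrays (Aquantile) leaves ratios unchanged by construction, so it was not run, nor were the gene list tests, print-tip loess from stated blocks, and alternatives on background, flags and foreground medians that the files do not hold. Each array pairs an exposed with an untreated culture, so the ratio is already paired. Signal over background limits the dim probes: 31.7% were not above empty spots on both arrays.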

Other observations

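Among the tests below, those of slide position, of a dye effect and of the skew of replicate 1 were chosen only after the results they bear on had been seen, and the patterns themselves were noticed in these data.

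Bright probes of the E1 series with consecutive numbers had similar ratios. Among the 1116 pairs of consecutive numbers in the 3 brightest eighths, the ratio of 1 probe on an array correlated with that of its neighbour on the other array at r = 0.326 (bootstrap 95% interval 0.261 to 0.386; rho 0.229). Over all 5977 consecutive E1 pairs, dim probes included, r was 0.0864, and 0.0428 at a distance of 2 numbers. Among the bright probes the value was 0.198 at a distance of 2 numbers, 0.108 at 4, 0.051 at 6 and 0.019 at 8. It was 0.019 at a distance of 20 and 0.056 at 50. Without probes whose mean ratio reached 2-fold, 1040 bright pairs gave r = 0.165 (0.113 to 0.211). Among E1 probes at 2-fold or more on both arrays, 7 consecutive pairs were higher and 3 were lower, against means of 0.48 and 0.068 when E1 probes of similar brightness were shuffled. Of 1000 shuffles, 0 reached the count of higher pairs (highest 4) and 1 reached that of lower pairs. In the E2 series 434 bright pairs gave r = 0.048 (-0.077 to 0.188), and all 3329 pairs gave 0.030. The bootstrap intervals of consecutive pairs, here and in the next paragraph, treat pairs as independent, which they are not. Adjoining pairs share a probe, so these intervals leave out part of the uncertainty.

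The tables argue against 3 technical explanations of this pattern, the position of the spots and similar brightness only in part. None of the bright consecutive E1 pairs shared an inferred printing block. In addition, 315 pairs of E1 probes next to each other inside a block, with numbers over 8 apart, gave r = -0.031 (-0.116 to 0.050). Both values argue against nearness of the spots inside a block. Positions that spots of different blocks may share were not tested. Partners matched on brightness reached the observed value in 0 of 1000 draws, with a highest r of 0.076. The loess curve was fitted to remove the dependence of the ratio on brightness within each array, so low values were likely beforehand. The draws show only that any such dependence left after loess did not give the observed r. A dye effect of each sequence would make the cross-array r negative once the swapped array is turned if it is alike in neighbours, which the r of 0.326, the value of the pattern itself and no separate test, excludes as the whole cause. If opposed in neighbours, it would make their r within each array negative, and this was 0.494 (0.411 to 0.565) on replicate 1 and 0.290 (0.207 to 0.369) on replicate 2. As a hypothesis, the E1 numbers may follow the order of genes on the chromosome, so that neighbours are transcribed together, or consecutive probes may target the same transcript; without a table from codes to genes neither was tested.

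More probes were higher than lower at 2-fold or more on both arrays, 75.8% (exact 95% interval 65.7 to 84.2). The exact intervals in this paragraph treat probes as independent, which they are not, so they are likely too narrow. An equal split is not the value without shared changes, because shuffling replicate 2 among probes of similar brightness gave 71.0% higher. Among probes above empty spots 76.5% (64.6 to 85.9) were higher, against 76.4% in the shuffles, so the planned comparison with 50% says nothing about dim spots. With median centring 66.7% (56.1 to 76.1) were higher, against 46.6% in the shuffles, which argues against the loess curve as the whole cause. Among probes above empty spots at 2-fold on 1 array alone, 73.9% (69.1 to 78.3) were higher on replicate 1 and 54.9% (49.5 to 60.2) on replicate 2. The lean may be a skew of replicate 1, but the shuffles point to this under loess and not under median centring, so it stays open. A difference between the pairs of cultures on the 2 arrays stays open as well.

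The 13 triplicate E1 probes also have 5 versions each, with suffixes 50 to 90 whose meaning is not stated. All 13 unsuffixed probes lay above empty spots, as did 8, 3, 3, 7 and 13 of the 13 versions with suffixes 50, 60, 70, 80 and 90. The suffixed version was the dimmer one in 12, 13, 13, 11 and 8 of 13 probes, in the same order. Because many versions with suffixes 50 to 80 did not lie above the 95th percentile of empty spots on both arrays, the size of their difference and their order are not measured. For suffix 90 the mean log2 intensity against the unsuffixed probe was -0.46 ± 0.95 (SD, 13 probes; exact sign-flip test, two-sided, adjusted over 5 tests, p = 0.10).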
